A study of Mus musculus with 4 samples.

How the data were processed

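Polyadenylated RNA from whole mouse testes at postnatal day 3 was sequenced by the authors as 100-base single-end reads, per the labels' protocols. The 4 libraries form 2 groups by genotype label: 2 libraries with the wild-type thyroid hormone receptor alpha 1 and 2 with a dominant-negative form of it. The animals came from crosses of AmhCre mice, a line that expresses Cre recombinase in Sertoli cells, with carriers of the TRαAMI allele of Thra, per the labels' protocols. Libraries are named here by group and replicate number. The labels give no litter, dissection day, sequencing lane or library batch, and nothing in them says whether each library came from a separate animal, so p-values measure only the spread between these samples.

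Per the submitters' processing notes, CASAVA 1.8.1, TopHat 1.4.0, HTSeq, DESeq2 and the genome build mm9 were used, with no role or order given. The authors deposited 1 table, handled here under the unit expected or estimated counts because 5 of the 16 lines below the genes hold percentages in the same columns. Its gene values are raw counts: each is a whole number, and the sum over genes equals the table's own total of uniquely mapped reads in genes in each of the 4 libraries. Rounding therefore changed nothing. The authors' counting set reads with several alignments apart, per the table's own category lines. The counter's version, mode, annotation and strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be separated, and near-identical gene copies (Rpl39l, Rpl10l, the Serpina3 and Stfa families) are uncertain.

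The table lists 22609 genes by symbol, of which 3868 had no count in any library. Gene counts summed to 13228903 and 10230512 in wild-type replicates 1 and 2 and to 11089136 and 15636832 in mutant replicates 1 and 2. Reads in no annotated gene made up 13.8% and 15.3% of the counted reads in wild-type replicates 1 and 2 and 17.3% and 14.4% in mutant replicates 1 and 2. Ambiguous reads made up 0.726%, 0.7%, 0.602% and 0.67% in the same order. These categories were kept out of library sizes and tests. Of all sequenced reads, the authors' table reports 93.1%, 92.4%, 87.9% and 92.7% as mapped. Gene positions are those of the GENCODE M1 annotation of NCBIM37, the assembly also called mm9, and 21627 of the symbols in the table occur in it.

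Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with trimmed mean of M values (TMM) normalisation. Genes were kept by edgeR's default expression filter, with a minimum count of 10 and a minimum total of 15, which left 14788 genes. The model held genotype alone, with the legacy and robust options off. The legacy option is on by default in this version, so switching it off was a stated choice. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p below 0.05 was called. Log2 fold changes are mutant minus wild type, and the standard error (SE) is the fold change divided by the square root of its F statistic. Expression is given as CPM, the counts scaled by edgeR with TMM-adjusted library sizes, as mean ± SD. Where a group held 15 or fewer counts, the ratio of summed counts is given with an exact 95% interval. Where a group held 0 counts, the fold is a lower bound set against 3 counts over the group. Intervals and bounds cover counting error only.

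The groups, the test, the lists of genes, the rule for named genes and a set of other settings were fixed before the data were examined. The named genes are Thra and Thrb, the 12 largest rises and 12 largest falls among called genes that separate the groups and have a mean log2 CPM of at least 1, up to 4 called members per list or 2 with the smallest p where none was called, and 10 genes always given (Sox9, Amh, Fshr, Klf9, Hr, Dio3, Ddx4, Mki67, Cdkn1b and Gja1). Not every gene that this rule takes is described in the text. Genes named outside it are said to be chosen after their values were seen. The 25 lists cover the cell types of the testis and of adjoining tissue, thyroid hormone action, proliferation, junctions, secreted factors, metabolism and housekeeping. Lists with at least 5 tested members, 23 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry were run beside it. A further 6 lists (skeletal muscle, mast cell, neutrophil, adipocyte, mesothelial and imprinted genes) were put together after the called genes were seen, so their tests are descriptions and not independent evidence.

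The other settings were DESeq2 1.42.0, limma voom, robust and legacy quasi-likelihood fits, other normalisations (median ratio, upper quartile, library size alone), other filters on low counts, a minimum fold change of 1.2, the replicate number as a block, and each library left out in turn. Settings chosen after seeing the data were the removal of muscle-tracking genes, in the same fit and in a refit, Acta1 as a covariate, and a correction of the trend on exon length. Acta1 was at 0.601 and 0.686 CPM in wild-type replicates 1 and 2 and at 875 and 222 CPM in mutant replicates 1 and 2. The covariate therefore takes up any difference between the mutant libraries, whatever its cause, and values under it are not specific to muscle. Muscle-tracking genes are those whose excess over the wild-type mean was at least 2 times larger in mutant replicate 1 than in mutant replicate 2, or which showed no excess in the latter. Settings meant for normalised values (another pseudocount or filter) did not apply to counts and were not run. A fit without 1 library keeps 1 residual degree of freedom, and the lone library of its group is then assumed to vary like the other group.

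Replicates were compared before use: over genes with at least 20 counts, the chi-square per degree of freedom was 8.33 for the wild-type pair and 9.88 for the mutant pair, so neither pair was 1 library deposited as a duplicate. The procedure was tested on simulated data for this comparison, with 14788 genes and 100 genes changed at each of 2 fold sizes. It recovered 85 of the 100 genes changed 2-fold and 52 of the 100 changed 1.5-fold, all in the right direction, with 5 false calls among 142. The simulated changes were placed in genes with a mean count of at least 50, so recovery among low genes is not covered. Counts were drawn from the dispersion trend alone, without the added spread of single genes or libraries. Recovery and the share of false calls may therefore be too favourable for the real data.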

Results

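The data are gene counts from 4 polyadenylated RNA libraries of whole testes taken from mice on postnatal day 3. In 2 libraries the thyroid hormone receptor alpha 1 was labelled wild type. In the other 2 it was labelled dominant negative, meaning a receptor form that blocks the action of the normal one, and the series' title restricts it to Sertoli cells, the somatic cells that surround germ cells in the seminiferous tubules. The series asks which genes in the testis depend on this receptor directly or indirectly. Gene counts per library were 13228903 and 10230512 in wild-type replicates 1 and 2 and 11089136 and 15636832 in mutant replicates 1 and 2. Over the 14788 tested genes, log2 CPM correlated at 0.988 within the wild-type pair and 0.985 within the mutant pair, against 0.952 to 0.971 between groups.

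Thra, the gene that carries the engineered allele (chromosome 11, 98601952 to 98630320, plus strand, mm9), was read at 398 and 257 CPM in wild-type replicates 1 and 2 and at 237 and 194 CPM in mutant replicates 1 and 2. Its log2 fold change was -0.60 ± 0.19 (SE) and did not pass the threshold (adjusted p = 0.0965), while it did at -0.89 without wild-type replicate 2 (adjusted p = 0.0463) and at -0.75 without mutant replicate 1 (adjusted p = 0.00558). The log2 fold change was -0.26 without wild-type replicate 1, the library with the most Thra (adjusted p = 0.319). Counts per gene cannot tell the normal from the mutant transcript, and other testis cells also hold Thra, so this value does not check the genotype labels. Thrb, the other receptor gene for the hormone, stood at 8.34 ± 0.540 CPM in wild type and 8.54 ± 0.154 CPM in mutant testes (SD, n = 2 each; adjusted p = 0.931).

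Germ cell markers were lower as a list in mutant testes and macrophage and leukocyte markers higher, by a set test with a preset correlation that neither list passed with an estimated correlation (p = 0.218 and 0.203). Of the Sertoli cell markers 5 of 29 fell, and of the mesothelium, rete and duct markers 5 of 15 rose, while neither list passed the set test. Stra8, which germ cells need for meiotic entry, fell 11.8-fold, and Dazl, an RNA-binding protein of germ cells, fell 2.54-fold. Cldn11, the claudin of the Sertoli cell tight junction, fell 2.33-fold, while Amh, the hormone by which fetal and neonatal Sertoli cells are recognised, differed by less than its error. The largest rises belonged to skeletal muscle genes, among them the skeletal actin gene Acta1, and adipocyte genes such as Fabp4 fell. By edgeR's quasi-likelihood test, 839 of 14788 genes were called, 466 higher and 373 lower in mutant testes, of which 200 and 152 changed more than 2-fold. Both mutant libraries lay on one side of both wild-type libraries in each called gene and in 57.3% of all tested genes.

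These counts depended on single libraries. Without wild-type replicate 1 the test called 34 genes higher and 40 lower, without wild-type replicate 2 it called 60 and 88, without mutant replicate 1 it called 517 and 332, and without mutant replicate 2 it called 818 and 477. In the full fit and all 4 leave-one-out fits alike, 42 genes were called, 22 higher and 20 lower. They include Cldn11, Dmrt1, Stra8, Dazl, Laptm5, Serpina3a and Fabp4, each described below. After removal of genes whose excess over wild type was at least 2 times larger in mutant replicate 1 than in mutant replicate 2, a step chosen after seeing the data, 375 higher and 373 lower calls were left.

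**Figure D1:**
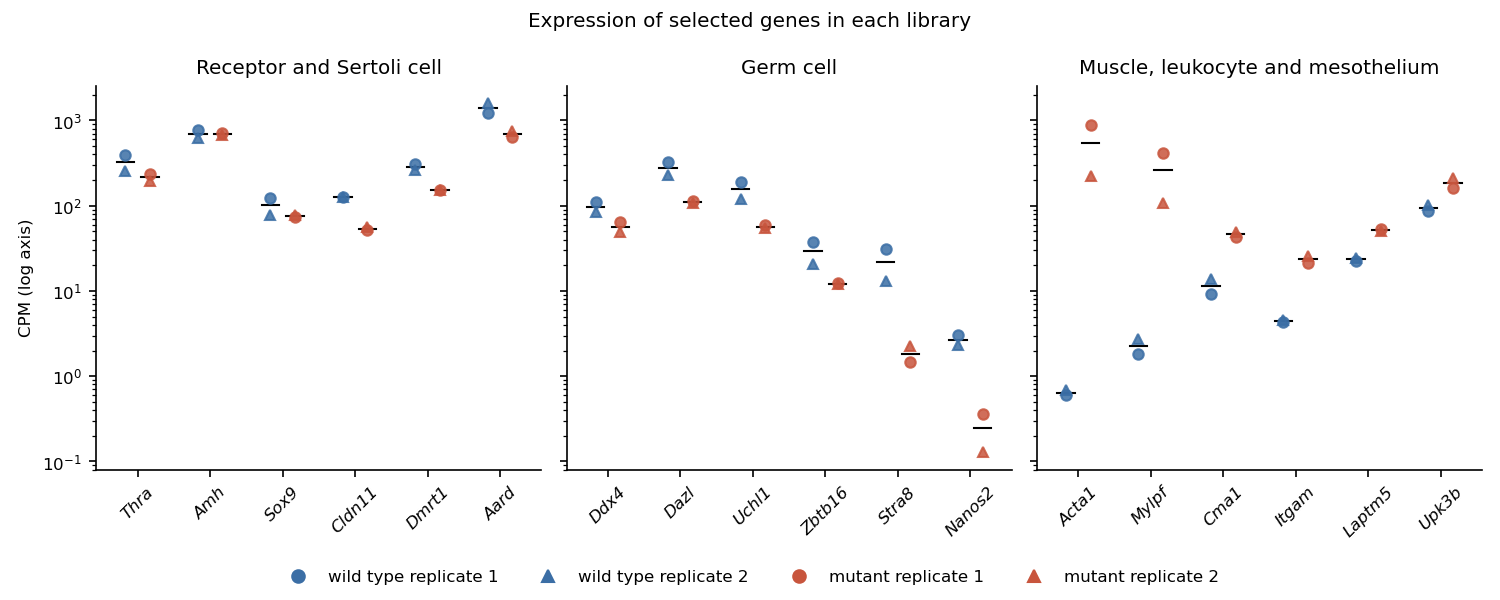
Expression in CPM of 18 genes in each of the 4 libraries, on a log axis, in 3 panels by gene group. Circles are replicate 1, triangles are replicate 2, blue is wild type, red is mutant and black bars are group means. Amh stayed between 618 and 777 CPM in all libraries, while Acta1 was 875 and 222 CPM in mutant replicates 1 and 2 and under 1 CPM in wild type.

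Germ cells at this age are prospermatogonia. Of the 32 germ cell markers tested, 18 fell, none rose and 14 were not called. Adjusted over the list alone, 24 fell and 1 rose. The median log2 fold change was -1.03, and camera placed the list below other genes (adjusted p = 9.56e-10), with p = 0.218 with an estimated correlation. Stra8 (chromosome 6, 34870163 to 34889342, plus strand) was read at 22.2 ± 12.6 CPM in wild type and 1.85 ± 0.550 in mutant testes (adjusted p = 0.0104). Sox3, a transcription factor of undifferentiated spermatogonia, fell by 4.00 ± 0.69 on the log2 scale (adjusted p = 0.0222). Nanos2, which keeps male germ cells out of meiosis, had 64 counts in wild type and 6 in mutant testes, a ratio of 12.1 (95% interval 5.26 to 34.2). The X-linked homeobox gene Rhox10 had 74 against 14 counts, a ratio of 5.99 (3.36 to 11.5). Among genes common to most germ cells, Ddx4, an RNA helicase, fell 1.74-fold (adjusted p = 0.0304). Chosen after their values were seen, Dazl (adjusted p = 0.00701), the ubiquitin hydrolase gene Uchl1 (2.75-fold, adjusted p = 0.0099) and the stem cell factor gene Zbtb16 (2.42-fold, adjusted p = 0.0356) fell as well. Kit, the receptor of differentiating germ cells, was read at a log2 fold change of -0.24 ± 0.13 and was not called (adjusted p = 0.28). Without wild-type replicate 1, which held more of these transcripts than wild-type replicate 2, 3 members were called lower, the calls of Sox3, Nanos2, Rhox10, Ddx4 and Zbtb16 were lost, and the log2 fold changes were -2.95 for Sox3, -2.79 for Stra8, -1.95 for Rhox10 and -0.77 for Zbtb16. Without wild-type replicate 2 the calls of Nanos2, Rhox10 and Ddx4 were lost. Dazl, Uchl1 and Stra8 were called in each of the 4 leave-one-out fits. Skeletal muscle genes summed to 3324 and 932 CPM in mutant replicates 1 and 2, against 97.2 and 104 CPM in wild-type replicates 1 and 2.

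Sertoli cell markers did not move as a list. Of 29 tested, 5 fell, 1 rose and 23 were not called, and adjusted over the list alone 6 fell and 3 rose. The median log2 fold change was -0.05, and camera gave an adjusted p of 0.206. Cldn11 (chromosome 3, 31048868 to 31063246, plus strand) went from 126 ± 0.446 to 54.0 ± 3.59 CPM (SD, n = 2 each), a log2 fold change of -1.22 ± 0.09 (adjusted p = 0.00237). Aard, an abundant Sertoli transcript, fell 2.02-fold (adjusted p = 0.0119), Etd, an X-linked gonadal gene, fell 1.92-fold (adjusted p = 0.0115), and Dmrt1, a transcription factor that maintains male fate in Sertoli cells and also acts in germ cells, fell 1.86-fold (adjusted p = 0.00579). Ptgds, the prostaglandin D synthase induced by Sox9, rose 1.69-fold (adjusted p = 0.0089). Sox9, the factor that directs Sertoli cell formation, was read at 101.0 ± 31.4 and 75.5 ± 2.28 CPM in wild type and mutant, and Fshr, the receptor of follicle-stimulating hormone, at 47.6 ± 9.93 and 51.2 ± 0.0695 CPM, and neither was called (adjusted p = 0.189 and 0.67), and the Sox9 value rested on wild-type replicate 1. Sox9 was at -0.06 without that library (adjusted p = 0.741) and passed at -0.71 without wild-type replicate 2 (adjusted p = 0.0418). Amhr2, the receptor gene for the Amh hormone, chosen after its value was seen, fell 1.72-fold (adjusted p = 0.00579). Without wild-type replicate 1 the list passed the threshold downward (adjusted p = 0.0279) and the call of Ptgds was lost, while the call of Etd was lost without wild-type replicate 2. With Acta1 as a covariate, chosen after seeing the data, the call of Aard was lost (adjusted p = 0.0789).

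Junction genes were mostly not called. Of 24 genes of cell junctions and the blood-testis barrier, 2 fell and none rose, over all genes and also adjusted over the list alone, with a median of -0.01 and an adjusted p of 0.572. These were Cldn11 and F11r, the junctional adhesion molecule A gene, which fell 1.41-fold (adjusted p = 0.0222) and lost its call without either wild-type library. Gja1, the main gap junction protein of Sertoli cells, had a log2 fold change of -0.03 ± 0.09. Factors that Sertoli cells secrete for other testis cells shifted upward: of 25 tested, 4 rose and none fell, and adjusted over the list alone 8 rose and 1 fell. The median was 0.28 and camera gave an adjusted p of 0.00977, with p = 0.0753 with an estimated correlation. The growth factor gene Igf2 rose 1.81-fold (adjusted p = 0.0444), the activin subunit gene Inhba 1.72-fold (adjusted p = 0.048), Ptgds as above, and the signalling gene Wnt4 1.58-fold (adjusted p = 0.0344). Igf2 and Wnt4 are also made by mesenchyme or other fetal tissues, and Igf2 stood at 1380 CPM in mutant replicate 1 and 873 in mutant replicate 2, the order in which these libraries held muscle transcripts. Without mutant replicate 1 the calls of Igf2, then at a log2 fold change of 0.49, and Inhba were lost, and without mutant replicate 2 that of Wnt4. The edgeR test called no member without wild-type replicate 1, and 1 without wild-type replicate 2. With Acta1 as a covariate, Igf2 stood at 0.27 and the list's median at 0.22 (adjusted p = 0.0616). Of 17 genes of follicle-stimulating hormone, androgen and estrogen signalling, Inhba rose and none fell (2 and 0 adjusted over the list alone, median 0.16, adjusted p = 0.206).

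Genes known to respond to thyroid hormone in other tissues gave little. Of 16 tested, 1 rose and none fell, while adjusted over the list alone 2 rose and 2 fell, with a median of 0.06 and an adjusted p of 0.775. The gene that rose was Hif3a, a hypoxia-inducible factor, which went from 17.6 ± 1.93 to 32.4 ± 3.59 CPM (SD, n = 2 each; adjusted p = 0.0225) and lost its call without either wild-type library. Klf9, a direct target of the receptor in brain and liver, had a log2 fold change of 0.29 ± 0.18 (adjusted p = 0.36), the corepressor gene Hr 0.30 ± 0.22 (adjusted p = 0.447) and the deiodinase gene Dio3 0.29 ± 0.40 (adjusted p = 0.693), with 34 and 47 counts for Dio3 in the wild-type and mutant groups. Among 21 receptors, cofactors, transporters and deiodinases edgeR called none, over all genes or over the list alone, with 4 at an unadjusted p below 0.05 and 0 by DESeq2 or limma voom (median 0.05, adjusted p = 0.463). The coactivator gene Ncoa1 was at 0.34 ± 0.10 (adjusted p = 0.075). Genes that neighbour Thra on chromosome 11 did not shift: of 15 tested, Erbb2, a growth factor receptor, rose 1.33-fold (adjusted p = 0.0495), a call lost without either wild-type library and without mutant replicate 1, and the other 14 were not called (1 and 0 adjusted over the list alone). That list had a median of 0.01 and a mean of -0.0034, of opposite sign, and an adjusted p of 0.842.

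Few markers of steroid-producing Leydig cells and of the tubule wall were called. Of 16 Leydig cell and steroidogenesis genes 1 fell, none rose and 15 were not called, and adjusted over the list alone 2 fell and 1 rose (adjusted p = 0.936). Vcam1, an adhesion molecule of these cells, fell 1.8-fold (adjusted p = 0.0194), a call lost without either wild-type library. Chosen after their values were seen, the steroid enzyme genes Cyp11a1 and Cyp17a1 and the hormone gene Insl3 had log2 fold changes of 0.31 ± 0.09, 0.09 ± 0.15 and -0.02 ± 0.17, none called. The Leydig list had a median of 0.06 but a mean of -0.05, and camera placed it downward. Of 12 peritubular myoid markers 1 rose, Cald1, an actin-binding protein, by 1.35-fold (adjusted p = 0.0291), and none fell. That call was lost without either wild-type library and without mutant replicate 1. Adjusted over the list alone 4 rose and 2 fell, and the median of -0.01 and mean of 0.15 differed in sign (adjusted p = 0.775). Of 15 endothelial markers edgeR called none, over all genes or over the list alone, with 1 at an unadjusted p below 0.05, 1 by DESeq2 and 0 by limma voom (median 0.07, adjusted p = 0.463). The endothelial genes Cdh5, a cadherin, and Erg, a transcription factor, had log2 fold changes of 0.36 ± 0.09 and -0.50 ± 0.22, and Cdh5 passed at 0.46 without mutant replicate 2 (adjusted p = 0.0289) and was at 0.26 without mutant replicate 1 (adjusted p = 0.315).

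Of 15 stromal and fibroblast markers edgeR called none over all genes, with 8 at an unadjusted p below 0.05, 4 by DESeq2 and 0 by limma voom, while adjusted over the list alone 6 rose and none fell. Their median was 0.30 and camera gave an adjusted p of 0.00977, with p = 0.287 with an estimated correlation and an adjusted p of 0.136 without wild-type replicate 2. The growth factor receptor gene Pdgfra of interstitial cells was at 0.36 ± 0.10 (adjusted p = 0.0676). Acta1 was at 875 and 222 CPM in mutant replicates 1 and 2 of the same comparison, while the stromal median log2 ratio of replicate 1 over 2 was 0.06. The stromal median log2 fold change was 0.34 without mutant replicate 1 and 0.36 with Acta1 as a covariate.

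Leukocyte transcripts were higher in mutant testes. All 16 macrophage and leukocyte markers tested had positive fold changes, of which 3 rose over all genes and 10 adjusted over the list alone, with none falling in either. The median was 0.66 and camera gave an adjusted p of 7.02e-06, with p = 0.203 with an estimated correlation. Laptm5, a lysosomal protein of blood cells (chromosome 4, 130469040 to 130492056, plus strand), went from 23.4 ± 0.960 to 52.3 ± 2.43 CPM (SD, n = 2 each; adjusted p = 0.00514) and was called in each leave-one-out fit. The complement gene C1qb rose 1.81-fold (adjusted p = 0.0461) and Csf1r, the receptor that macrophages need, 1.58-fold (adjusted p = 0.049), and both lost their calls without either wild-type library and without mutant replicate 2, where their log2 fold changes were 0.53 and 0.44. Without either wild-type library or mutant replicate 2, 1 member was called, and without mutant replicate 1, 7 were. Of the red blood cell markers only Alas2 and Slc4a1 were tested, with log2 fold changes of 0.34 ± 0.33 and 0.11 ± 0.55, and neither was called.

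Several muscle, fat and mesothelial transcripts also differed between the groups. Of 13 muscle and brown fat markers tested, 8 rose and 2 fell, and adjusted over the list alone 9 rose and 3 fell, with a median of 4.52. Camera gave an adjusted p of 0.0124, with p = 0.308 with an estimated correlation, and the call was lost without wild-type replicate 1 (adjusted p = 0.125) and without wild-type replicate 2 (adjusted p = 0.109). Acta1 (chromosome 8, 126415669 to 126418651, minus strand) was at 0.601 and 0.686 CPM in wild-type replicates 1 and 2 and at 875 and 222 CPM in mutant replicates 1 and 2, a count ratio of 770 (467 to 1376). The myosin gene Myh8, the troponin gene Tnnt3 and the myosin light chain gene Mylpf, all of skeletal muscle, rose 130-fold, 127-fold and 117-fold. Their log2 fold changes of 7.03, 6.99 and 6.87 became 5.81, 5.89 and 5.58 without mutant replicate 1, that of Acta1 went from 9.72 to 8.42, and the calls of Myh8, Tnnt3 and Mylpf were lost without either wild-type library and by limma voom. The members that fell were fat cell genes, Adipoq with 100 against 7 counts (ratio 16.2, interval 7.57 to 41.3) and Fabp4, chosen after its value was seen, with a 4.94-fold fall (adjusted p = 0.00237). Of 15 mesothelium, rete and duct markers 5 rose and none fell, and adjusted over the list alone 6 rose and 1 fell (median 0.22, adjusted p = 0.168). The members that rose are mesothelial or surface epithelial genes: Lrrn4 rose 2.42-fold (adjusted p = 0.0104), Upk1b 2.18-fold (adjusted p = 0.0172), Krt19 2.01-fold (adjusted p = 0.0206) and Upk3b 1.97-fold (adjusted p = 0.0127). Without wild-type replicate 1 edgeR called none of the 15, although the list as a whole then passed (adjusted p = 0.03), as it did without mutant replicate 1 (adjusted p = 0.0162). Without mutant replicate 2 the median was 0.08 (adjusted p = 0.9), with 5 members called higher and 3 lower. The call of Upk3b was lost without wild-type replicate 2 too. Adipoq lost its call without either wild-type library.

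**Figure D2:**
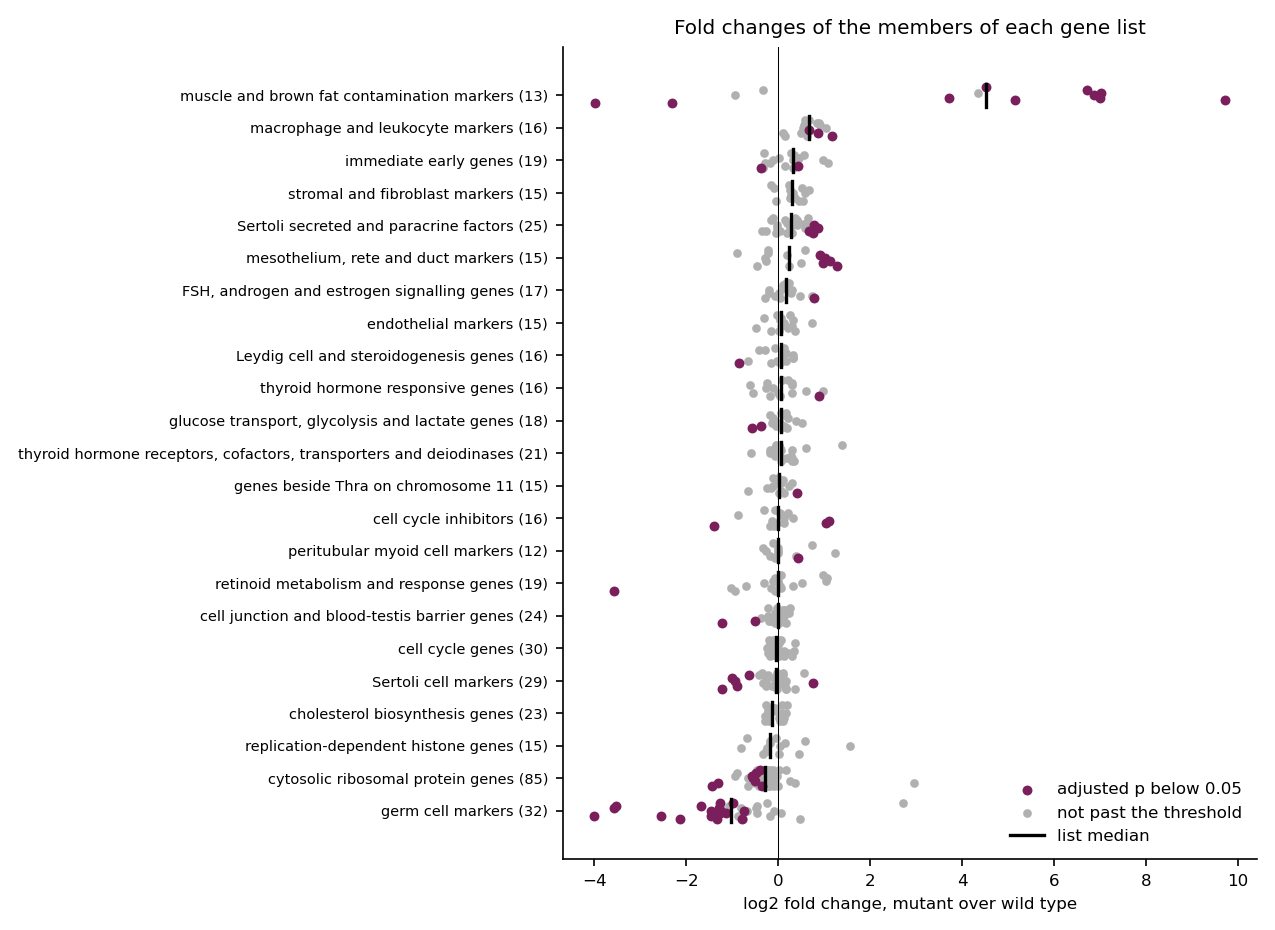
Log2 fold change, mutant over wild type, of each tested member of the 23 gene lists tested with camera, with the number tested in parentheses. Purple points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. Germ cell markers have the lowest median, -1.03, and muscle and brown fat markers the highest, 4.52, with 2 members of the latter list below 0 and called.

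The 12 largest rises by the naming rule all belong to striated muscle or are made by it. Myl2, Hfe2, Xirp2, Lmod2 and Ampd1 had no counts in wild type and were at least 132-fold, 77.3-fold, 40-fold, 35.3-fold and 33.5-fold higher. These bounds were 58.5-fold, 28.5-fold, 27.5-fold, 16-fold and 19.5-fold without mutant replicate 1, and 238-fold, 147-fold, 57.8-fold, 62.8-fold and 53.5-fold without mutant replicate 2. Without wild-type replicates 1 and 2 they were 2.31 and 1.77 times smaller, since fewer reads then stand behind the 0. Myl1, Sln, Atp1b4 and Csrp3 had 1 count each in wild type and 2695, 596, 478 and 363 in mutant testes, ratios of 2378 (426 to 93953), 526 (94 to 20804), 422 (75.3 to 16692) and 320 (57.1 to 12685). Tnnc2 and Actc1 had ratios of 300.2 (175 to 564) and 211 (102 to 527), and Acta1 is given above. Without wild-type replicate 1 none of these 12 genes passed, without wild-type replicate 2 only Acta1 did, and limma voom left Xirp2, Lmod2 and Ampd1. Mutant replicate 1 held most of these counts, and without it the log2 fold changes of Myl1, Sln, Atp1b4, Csrp3, Tnnc2 and Actc1 went from 11.06, 8.84, 8.53, 8.15, 8.36 and 7.89 to 9.73, 7.62, 7.01, 5.76, 7.09 and 4.77. Of the 466 genes that rose, 91 had an excess over wild type at least 2 times larger in mutant replicate 1 than in mutant replicate 2, as most skeletal muscle genes did, and 375 did not. Among those 375, by a rule added after the data were seen, the 12 largest rises included the neutrophil genes Stfa1, S100a9, S100a8 and Itgam, the mast cell gene Cpa3, the chemokine gene Ccl6 and the ficolin gene Fcna. Itgam, an integrin of myeloid cells, went from 4.43 ± 0.108 to 23.5 ± 3.13 CPM, and Cpa3, a mast cell protease, from 5.75 ± 2.82 to 30.4 ± 2.00 CPM (SD, n = 2 each; adjusted p = 0.00444 and 0.00579). The others were BC100530, Ptpn7, Prss34 and the muscle genes Pvalb and Mybpc2, which fell short of that ratio, so the 375 still hold muscle transcripts.

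Lists put together after the called genes were seen describe these transcripts further and are not independent evidence. Of 24 skeletal muscle genes 19 rose and none fell (median 5.06, adjusted p = 5.33e-17, p = 0.172 with an estimated correlation). Myh3, Myog and Chrna1, which embryonic or uninnervated muscle expresses, were not called and were concentrated in mutant replicate 1: Myog had 0 counts in wild type and 266 in mutant testes, at least 78.2-fold more (adjusted p = 0.0817), and without mutant replicate 1 at least 15.5-fold more (adjusted p = 6.99e-05). Of 8 mast cell markers 4 rose and none fell (median 0.86, adjusted p = 0.00206, p = 0.313 with an estimated correlation), among them the proteases Cma1, 4.08-fold, and Tpsb2, 4.52-fold. Of 7 neutrophil markers 5 rose and none fell (median 2.27, adjusted p = 4.38e-06). Camera with an estimated correlation gave the neutrophil list p = 0.0396, which did not pass after adjustment (adjusted p = 0.151). Among 13 mesothelial markers, 10 of them in the lists above, 6 rose and none fell (median 0.69, adjusted p = 2.40e-05, p = 0.101 with an estimated correlation). Of 13 adipocyte markers none rose and 5 fell (median -0.33, adjusted p = 0.0016, p = 0.0782 with an estimated correlation), among them Cidec, a lipid droplet protein, with 38 against 1 count (ratio 43.1, interval 7.28 to 1745), and Cfd, with 24 against 0 counts, at least 9.07-fold less, or 5.33-fold and 3.74-fold without mutant replicates 1 and 2. Without either wild-type library the call of Cidec was lost.

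**Figure D3:**
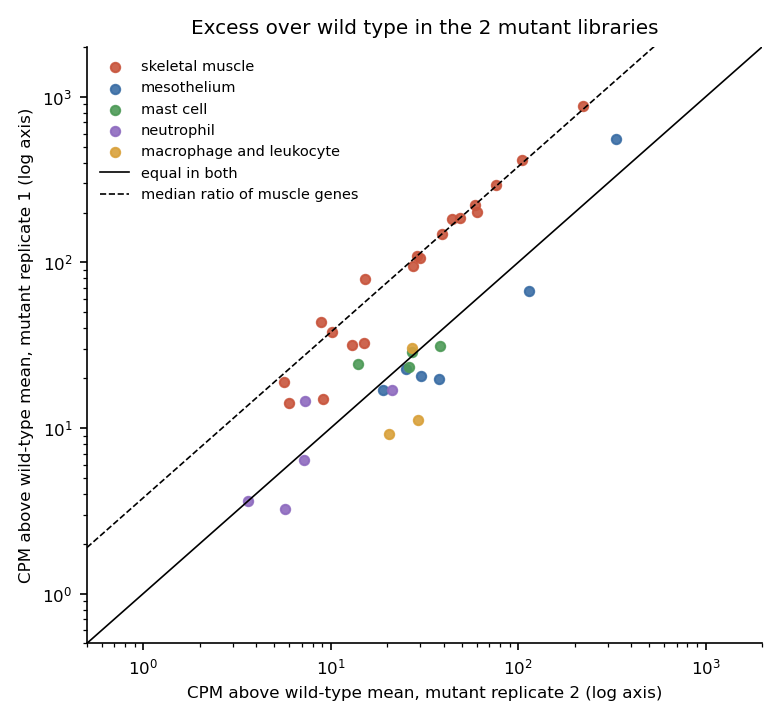
CPM above the wild-type mean in mutant replicate 2 (x axis) and mutant replicate 1 (y axis), on log axes, for the called higher genes of the skeletal muscle, mesothelial, mast cell, neutrophil and macrophage lists, coloured by list. The solid line marks equal excess and the dashed line the median ratio of the muscle genes, 3.79. The 18 called genes of the other lists had a median ratio of 0.891, with an SD of the log2 ratio of 0.653. Only called genes are plotted, and a call favours alike values in both mutant libraries.

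The 12 largest falls mixed germ cell genes with others. Sox3, Stra8 and Adipoq are given above. Serpina3a, a member of a serine protease inhibitor family whose copies share sequence (chromosome 12, 105350934 to 105360106, plus strand), had the smallest adjusted p of all genes, 7.79e-04, and went from 69.6 ± 7.06 to 9.90 ± 1.52 CPM (SD, n = 2 each). Rspo2, which amplifies Wnt signals, fell 10.1-fold (adjusted p = 0.00838), Asb9, a ubiquitin ligase subunit, fell 5.77-fold (adjusted p = 0.00993), Fmr1nb fell 5.06-fold (adjusted p = 0.0109) and Pramef12, a gene of spermatogonia, fell 5.01-fold (adjusted p = 0.00513). Tmsb15b1, Lrrc23 and Ccdc67 had few mutant counts, with ratios of 14.7 (6.87 to 37.7), 12.7 (6.44 to 28.6) and 6.35 (3.64 to 11.8). Dao, an amino acid oxidase, had 157 counts in wild type, none in mutant replicate 1 and 28 in mutant replicate 2, and Tmsb15b1 had none in mutant replicate 1 and 7 in mutant replicate 2. The log2 fold changes of Dao and Tmsb15b1 were -2.67 and -3.84, and -1.89 and -3.09 without mutant replicate 1. Tmsb15b1, Lrrc23, Ccdc67, Fmr1nb and Dao lost their calls without either wild-type library, and Rspo2 and Asb9 without wild-type replicate 1. DESeq2 did not call Dao (adjusted p = 0.604).

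Of 30 cell cycle genes edgeR called none, over all genes or over the list alone, with 4 at an unadjusted p below 0.05, 1 by DESeq2 and 0 by limma voom (median -0.04, adjusted p = 0.715). Mki67, a marker of dividing cells, had a log2 fold change of 0.21 ± 0.12, and Ccnd2 and Ube2c 0.30 ± 0.09 and -0.24 ± 0.08. Of 16 cell cycle inhibitors 2 rose and 1 fell (3 and 1 adjusted over the list alone, median -3.00e-04, adjusted p = 0.935). Cdkn1a, the p53 target that encodes p21, rose 2.13-fold (adjusted p = 0.0296), Cdkn1c, the imprinted gene of p57, rose 2.04-fold (adjusted p = 0.0166), and Cdkn2a, the gene of p16 and p19Arf, fell 2.62-fold (adjusted p = 0.0104). All of these calls were lost without wild-type replicate 1, and those of Cdkn1a and Cdkn1c without wild-type replicate 2. Cdkn1a stood at 42.0 CPM in mutant replicate 1 and 27.3 in mutant replicate 2, an excess 2.31 times larger in the library with more muscle transcripts. With Acta1 as a covariate, which takes up any difference between the mutant libraries, Cdkn1a was not called (log2 fold change 0.55, adjusted p = 0.411). Cdkn1b, which encodes the p27 inhibitor linked to the end of Sertoli cell division, had a log2 fold change of 0.07 ± 0.10 (adjusted p = 0.707).

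Of 19 retinoid metabolism and response genes, Stra8 fell and the other 18 were not called (2 rose and 3 fell adjusted over the list alone, median -0.01, adjusted p = 0.9). Of 23 cholesterol biosynthesis genes edgeR called none, over all genes or over the list alone, with 1 at an unadjusted p below 0.05 and 0 by DESeq2 or limma voom (median -0.14, adjusted p = 0.437). The enzyme genes Acat2 and Mvk were at -0.28 ± 0.12 and -0.23 ± 0.11, and without wild-type replicate 2 the list passed downward (median -0.28, adjusted p = 0.00121), while without wild-type replicate 1 its median was 0.07 (adjusted p = 0.555). Of 18 glucose and lactate genes none rose and 2 fell (1 and 2 adjusted over the list alone, median 0.05, adjusted p = 0.935): the lactate exporter gene Slc16a3 fell 1.48-fold (adjusted p = 0.0226) and the lactate dehydrogenase subunit gene Ldhb fell 1.29-fold (adjusted p = 0.0461). Of 19 immediate early genes Fosl2 rose 1.35-fold (adjusted p = 0.0468) and Ctgf, which also responds to Hippo signalling, fell 1.3-fold (adjusted p = 0.0462), with 2 and 1 adjusted over the list alone, a median of 0.32 and an adjusted p of 0.0966. The immediate early list passed without wild-type replicate 2 (adjusted p = 0.0024) and had an adjusted p of 0.736 without wild-type replicate 1. The calls of Ldhb and Ctgf were lost in each leave-one-out fit, that of Fosl2 without either wild-type library and without mutant replicate 1, and that of Slc16a3 without wild-type replicate 1.

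Replication-dependent histone transcripts lack a poly(A) tail in dividing cells. Of 15 tested edgeR called none, over all genes or over the list alone, with 0 at an unadjusted p below 0.05 and 0 by DESeq2 or limma voom (median -0.17, adjusted p = 0.668). Hist3h2a was at -0.32 ± 0.18 and Hist1h2bc at -0.27 ± 0.16. Each fit without 1 library filtered the genes anew and let in genes expressed in any 1 library. Without mutant replicate 2, 30 histone genes entered, with a median of 1.12, and without mutant replicate 1, 14 entered, with a median of -0.40. Without wild-type replicates 1 and 2, 31 and 29 entered, with medians of 1.12 and 0.47. These medians cover different genes, some let in by a high value in 1 library, so they do not show a shift of the list between the groups. Over the 15 genes of the full fit, the median log2 ratio of replicate 1 over 2 was 0.41 in mutant and 0.03 in wild type. The list was thus higher in mutant replicate 1 than in mutant replicate 2, and the cause was not tested.

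Ribosomal protein genes were lower by a small amount. Of 85 cytosolic ribosomal protein genes 8 fell and none rose, and adjusted over the list alone 14 fell and 1 rose. The median was -0.30, with 80 members negative, and camera gave an adjusted p of 1.69e-10, with p = 0.173 with an estimated correlation. The largest falls were in Rpl39l and Rpl10l, retrogene copies used in male germ cells, at 2.7-fold (adjusted p = 0.00615) and 2.48-fold (adjusted p = 0.0231). The ordinary subunit gene Rpl36al fell 1.46-fold (adjusted p = 0.0296). Across genes, which are not independent replicates, fold change rose with exon length (Spearman 0.296 over 14458 genes), and ribosomal protein genes are short. The calls as a whole were split by length too. Median exon length was 4618.5 bases in genes called higher and 2190 in genes called lower, against 3667 in tested genes. After correction of the trend on exon length, an alternative chosen after seeing the data, the ribosomal median was -0.13 (adjusted p = 1.02e-04), and 2 members were called lower. With Acta1 as a covariate the median was -0.15 (adjusted p = 3.87e-04), again with 2 members called lower. Without wild-type replicate 1, wild-type replicate 2, mutant replicate 1 and mutant replicate 2, in turn, 1, 2, 3 and 15 members were called lower. Rpl36al lost its call without either wild-type library and without mutant replicate 1, and Rpl10l lost it without wild-type replicate 1.

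By camera, 6 of the 23 lists passed with the preset correlation and 0 with an estimated correlation, where the smallest p was that of Sertoli secreted factors and the adjusted p was 0.958 for each list. The fry test, which asks whether a list's genes move on balance one way, also called 0 lists after adjustment. No mitochondrially encoded gene is in the table, so that list gave no value. The table holds whole testes, so a lower count of a cell type's transcripts can reflect fewer cells or less transcript per cell, and these data do not separate the possibilities.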

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

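This value was chosen for a closer look by a comparison made after the library totals were seen. Reads that fell in no annotated gene, which the comparisons above do not use, made up 17.3% of the counted reads in mutant replicate 1, above the 13.8% and 15.3% of wild-type replicates 1 and 2, while mutant replicate 2 had 14.4%, within the wild-type range. The same library had the lowest share of mapped reads, 87.9%, against 92.4% to 93.1% in the others, and the highest Acta1, 875 CPM. The excess appeared in 1 of 2 mutant libraries, and no test was made of it.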

How the results depend on the processing

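The settings that changed the test, the scaling or the filter were fixed beforehand, while the muscle and length settings were chosen only after the results were seen. Calls, 466 higher and 373 lower as reported, stayed within 1.5 times under DESeq2 (601 and 403), robust and legacy fits, other scalings, a CPM filter and the replicate block (512 and 338, of which 409 and 301 were among those reported). The replicate numbers are not said to pair libraries, and their differences within groups correlated at -0.03 across genes. With that block 89 of the named calls held, 5 were lost and 5 genes were newly called, among them Thra at -0.57 (adjusted p = 0.028). The median log2 fold change of all genes, -0.00601 as reported, lay between -0.0135 and 0.0087 under other scalings. Limma voom called 309 higher and 272 lower. No filter on low counts, which tests more genes, gave 282 and 219, and a minimum fold change of 1.2, a stricter question, gave 145 and 115. Leaving out 1 library ranged from 34 to 818 higher and from 40 to 477 lower. The smallest counts came without wild-type replicate 1 (34 and 40, of which 26 and 30 were among those reported) and the largest without mutant replicate 2 (818 and 477, of which 408 and 276 were). A lone wild-type library leaves the spread to be taken from the mutant pair, which differs in muscle transcripts. Dropping muscle-tracking genes from the same fit left 375 and 373, and a refit without them gave 750 and 478. That refit favours calls by construction, since genes were removed for differing between the mutant libraries, and the median trended biological coefficient of variation fell from 0.108 to 0.0886. With Acta1 as a covariate the counts were 190 and 101, with 1 residual degree of freedom, and with the length trend corrected 307 and 228. Of the list tests, 6 as reported, 0 passed with an estimated correlation and 0 with fry, and 6 to 8 in the other runs. The medians are the same in those fits and only the calls were lost: germ cell markers -1.03, stromal 0.30, macrophage 0.66, muscle and brown fat 4.52, Sertoli secreted factors 0.28 and ribosomal protein genes -0.30. Over the leave-one-out fits the stromal median ranged from 0.17 (not called) to 0.41 and the muscle median from 3.36 to 5.31 (not called). Sertoli secreted factors went to 0.22 with the Acta1 covariate and were no longer called. Dao turned from -2.67 to 0.65 with that covariate, the only named call to reverse under any setting. Of 94 named genes called, 91 of the 93 tested were still called by DESeq2, 68 by limma voom and with the minimum fold change, 73 in the robust fit, 79 with no filter, 66 with the Acta1 covariate, 77 with the length correction, 24 of 93 without wild-type replicate 1, 39 of 93 without wild-type replicate 2, 86 without mutant replicate 1 and 88 without mutant replicate 2. The cause was not tested for changes not explained here. The self-test recovered 52 of 100 genes changed 1.5-fold, so changes of that size can be missed, and smaller changes were not simulated.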

Other observations

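The tests in this part were chosen only after the results they concern were seen, except the comparison of ribosomal protein genes with lists matched for exon length and expression, whose prediction was written before its value was known.

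Imprinted genes of the fetal growth network are high in growing fetal and neonatal tissues and fall with age. Of 20 tested 12 rose, none fell and 8 were not called, with a median log2 fold change of 0.59. Plagl1, a regulator of the network, went from 185 ± 28.3 to 373 ± 30.2 CPM (SD, n = 2 each; adjusted p = 0.00717), and Grb10, a growth inhibitor, rose 1.82-fold (adjusted p = 0.00579), each called in every leave-one-out fit. H19, the noncoding neighbour of Igf2, rose 2.23-fold (adjusted p = 0.0226) and lost its call without either wild-type library, and Dlk1 was read at a log2 fold change of 0.29 ± 0.11 (adjusted p = 0.168). Camera gave 2.79e-08 for this list, with p = 0.0896 with an estimated correlation, a value that says nothing about the hypothesis that the network rose as a whole, because the list was chosen after Plagl1, Grb10, Igf2 and Cdkn1c had been seen to rise. The excess of the 12 called genes in mutant replicate 1 over 2 had a median log2 ratio of 0.327, against 1.92 for muscle genes. A call favours genes with alike values in both mutant libraries, and over all 20 members the median of 0.40 lay 1.52 below that of the muscle genes, within the summed SDs of 2.18, so the muscle RNA as a source stays open. H19 and Igf2, the called members with the most CPM of excess, had ratios of 2.36 and 3.01.

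The complement gene C3 went from 34.5 ± 5.09 to 108 ± 18.4 CPM (SD, n = 2 each; adjusted p = 0.00444). Lox, which crosslinks collagen, rose 2.09-fold (adjusted p = 0.00513), and Igfbp5, an insulin-like growth factor binding protein, rose 2.42-fold (adjusted p = 0.00579) but lost its call without wild-type replicate 1. The lectin receptor gene Clec12b fell 3.6-fold (adjusted p = 0.00237) and Dmrta1, a relative of Dmrt1, fell 2.48-fold (adjusted p = 0.00444). C3, Lox, Clec12b and Dmrta1 were called in each leave-one-out fit. These genes were chosen after their values were seen.

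Striated muscle carried along at dissection is one hypothesis for the muscle genes, and an effect of the genotype on muscle-like cells of the testis is another. If a single tissue of fixed make-up were the source, the ratio of excess between the mutant libraries would be alike for all muscle genes. The SD of its log2 over 23 genes was 0.730, above the bound of 0.5 set for it. Myh3, Myog and Chrna1 were at 4.09, 3.43 and 3.15 against a median of 1.92. Pieces of differing maturity could also spread the ratio, and a genotype effect could keep it narrow, so it cannot decide the question. Of 12 peritubular myoid markers, which belong to muscle-like cells of the tubule wall, 1 rose and none fell. Their median log2 fold change was -0.01, so no rise of these markers as a set was seen. For 18 called leukocyte, mast cell and mesothelial genes the median log2 ratio was -0.167. For the 43 of all 44 tested members with an excess it was -0.81, 2.73 below the muscle genes and outside the summed SDs of 1.61. The SD of these members leaves out 8 with an excess in mutant replicate 2 alone. The values argue against 1 tissue of fixed make-up as the source of both sets. Pieces of differing make-up could give such ratios, so muscle with adjoining tissue is not excluded. Genotype and dissection cannot be told apart in 2 libraries per group without such labels.

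Germ cell markers could be lower because the mutant samples held other tissue. Dilution by muscle RNA predicts lower values in mutant replicate 1, the library with more of it. The median log2 ratio of mutant replicate 1 over 2 was 0.313, with 29 of 32 markers higher in replicate 1. Between wild-type replicates 1 and 2, which held alike amounts of muscle transcripts, the same median was 0.53. The mutant ratio lies within that replicate spread, so it cannot decide the question. Dilution of whole tubules by any tissue predicts an equal loss of Sertoli markers, if the genotype leaves Sertoli transcripts unchanged. The Sertoli median lay 0.980 above the germ cell median (permutation p = 1.00e-05, the smallest possible with 100000 draws, with genes taken as independent). Germ cell markers thus fell more than Sertoli markers, which an equal dilution alone does not give. The mutant receptor is restricted to Sertoli cells, so their markers are no neutral reference. The Leydig cell list, outside that restriction, had a median of 0.06, with quartiles of -0.19 and 0.16. The germ cell quartiles were -1.37 and -0.48. Other tissue mixed into the testis would lower both lists. These values argue against such dilution as the whole cause, unless Leydig cell transcripts rose to match. Neither the gap to the Sertoli markers nor the replicate ratio separates fewer germ cells from less transcript per cell. The medians include wild-type replicate 1, without which the germ cell median was -0.73, the Sertoli median -0.12 and the Leydig median 0.02.

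Ribosomal protein genes are short, and a bias by transcript length might lower them, since fold change rose with exon length between each mutant and each wild-type library (Spearman 0.21 to 0.31). Of 10000 lists matched for exon length and mean expression, 0 had a median as low as that of the ribosomal genes, -0.30, with a lowest of -0.242 and a median of -0.116. The draws took genes as independent and so do not allow for ribosomal genes that move together. Camera with an estimated correlation gave the ribosomal list p = 0.173. With genes taken as independent, the values argue against length as the whole cause and leave room for it as part. Without mutant replicate 1, the library with the lowest mapped share, the median was -0.227, which argues against that library as the sole source. Whether the length trend itself is technical was not tested.

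Within 5 Mb of Thra 11 of 228 genes were called, against 818 of 14229 elsewhere, an odds ratio of 0.831 (one-sided Fisher exact p = 0.764). The log2 ratio of excess of the 5 called adipocyte genes, wild-type replicate 1 over 2, had an SD of 0.524. Fold change correlated with exon length at -0.09 between the wild-type libraries and -0.11 between the mutant libraries.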
